A study of Mus musculus with 8 samples.

How the data were processed

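RNA of the most distal colon of male BALB/c mice, an inbred strain, at 5 weeks of age was measured on 8 Affymetrix MoGene 1.0 ST arrays, which carry probes along the whole transcript. In the AA group (4 arrays) appendicitis was induced and the appendix was removed 1 week later. In the SS group (4 arrays) 2 sham operations were done 1 week apart. Per the labels, each array held an individual colon sample, extracted and hybridised on its own with 100 ng of RNA labelled. The labels do not name the animals, so p-values measure the spread between these samples. The labels also name 2 batches, and each batch held 2 AA and 2 SS arrays. The name of the deposited list of raised sets gives 3 days after appendicectomy, and the array labels give no day of harvest.

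The authors deposited one log2 expression value per probe set and array. Per the submitters' processing notes, these came from RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises probes), with Affymetrix Power Tools and Partek 6.4 named as tools. The genome build, the annotation release and any filter are not given in the sources used here, so no coordinates are printed. The deposited log2 values ran from 2.85 to 14.72, and the array medians from 6.93 to 6.99. Over the named probe sets the means of batch 1 and batch 2 differed by at most 0.00006, and only 6 components of the 8 arrays carried variance. The values therefore entered with the batch means already removed, a step not given in the sources used here. Such a step leaves the differences between AA and SS as they were, because both batches held equal numbers of each group. It also lowers the other arrays of a batch wherever one array carries a high private signal. Arrays give no read depth, and their number limits the precision.

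The authors also deposited a table of gene sets raised in AA. Per the file headers it holds the enrichment score of each set (NES, the normalized enrichment score of gene set enrichment analysis) with a nominal p-value and a false discovery rate q-value. It holds names of sets, not of genes. The median difference over a deposited list of raised genes, planned before the data were examined, was therefore not computed, and the part of the naming rule that relied on it was not used. The scores are quoted only as the authors' own.

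The value table held 23442 probe sets. The platform annotation of the series paired 19713 of them with genes. Of these, 18154 had 1 gene symbol and were tested, 1559 had several and were not named, and the other 3729 were unnamed here. Entrez identifiers of 18092 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, used for names alone, and this changed 0 symbols. For gene lists, each of the 16645 genes was represented by its probe set with the highest mean over the 8 arrays.

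Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on the deposited log2 values, with batch and group as terms and 5 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 18154 probe sets, with 0.05 as the threshold and no filter on dim probe sets. A difference is the AA mean minus the SS mean on the log2 scale, with its standard error from limma. The deposited batch-centred values make the batch term 0 for every probe set, and keeping it in the fit gives the residual degrees of freedom their right number. Before the data were examined, 52 gene lists (cell types, other tissues and pathways) were fixed; 810 of their 974 entries were measured, and the 51 lists with at least 5 measured members were tested. The list of red blood cell genes was too small. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 51 lists. Camera with a correlation estimated per list and limma's fry were alternatives. Counts "adjusted over the list alone" used limma's p-values of the list's own members. An exact two-sided permutation of the group labels within batches was added for the list means. It has 36 relabelings, so its smallest p is 0.0556 and it cannot fall under 0.05.

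The genes named in the text were chosen by a rule written before the data were examined. In each direction these were the 12 probe sets with the largest difference among those past the threshold and of one sign in both batches, filled up by the smallest unadjusted p where fewer passed. Added to these were the 4 members with the smallest p of each called list, and a fixed panel of 20 cytokine and defence genes, of which 16 were measured. As 11 of the 12 lower probe sets belonged to 1 gene, Hmcn1, a reading with 1 probe set per gene was added after the data were seen. Genes named outside the rule are said to be so.

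Other settings planned were no batch term, a replicate block, a filter at the median level, all probe sets, quantile normalization, median centring, an intensity trend with robust variance, array weights, each array left out, each batch alone, and 2 other thresholds. Settings added after seeing the data left out a pair of arrays that stood apart (AA replicate 3 with SS replicate 1, or AA replicate 2 with SS replicate 4), used 1 probe set per gene, or took the mean of the mesothelium, macrophage or adipose list as a covariate. The same fit was tested on simulated data with 200 changed probe sets among 18154 in 4 and 4 arrays. It recovered 42.5% of them at a 1.5-fold change, 86.0% at 2-fold and 97.5% at 4-fold. In simulated lists, camera at its preset correlation called 5 of 5 shifted and 1 of 15 unshifted lists, camera with an estimated correlation 5 and 0, and fry 5 and 1. The chance of non-overlapping groups was simulated with 100000 sets of normal values centred within batches. Simulated genes were drawn independently of one another, unlike the real ones.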

Results

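The series asked how the distal colon of mice that had been through experimental appendicitis and removal of the appendix (AA) differed from that of mice with sham operations (SS). It comprised 8 arrays, 4 of AA and 4 of SS, in 2 batches with 2 arrays of each group. Expression values of any 2 arrays correlated across probe sets at 0.974 to 0.995. The first component held 31.9% of the variance and set AA replicate 3 and SS replicate 1 apart from the other 6 arrays. The second held 27.4%, with AA replicate 2 at one end.

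In AA colon, interferon-induced genes and genes of fibroblasts and the extracellular matrix lay above their SS levels, and genes of B cells and lymphoid follicles lay below. Every measured member of the first 2 lists was higher in AA, with median log2 differences of 0.77 over 26 genes and 0.45 over 24 genes. Of the B cell and follicle genes 15 of 16 were lower, with a median of -0.33, which was -0.55 in batch 1 and -0.01 in batch 2. Among interferon list means, SS replicate 1 (0.10) lay above AA replicate 4 (0.06). The 95% interval of the list mean difference included 0 for the interferon list (-0.03 to 1.61) and the B cell list (-0.82 to 0.03). Smooth muscle genes were also higher, by a median of 0.38 over 20 genes. Adipose genes were lower by a median of -0.64 over 14 genes, 0 of them at an unadjusted p under 0.05 in limma. The adipose median was -1.34 in batch 1 and -0.12 in batch 2, and the list mean was highest in SS replicate 1, at 1.45. No single probe set passed the threshold over all genes. In limma 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.199. At an unadjusted p under 0.05, 977 were higher and 490 lower, 1467 together against 907.7 expected by chance in both directions together. In this fit the excess lay mainly among the higher ones, and 60 of the 490 lower ones belonged to 1 gene, Hmcn1. Read with 1 probe set per gene, 944 of 16645 genes were higher and 383 lower. With quantile normalization the counts of probe sets were 953 and 781. Without SS replicate 1 they were 1013 and 1121, so the excess of higher probe sets turned. All 4 AA arrays lay above all 4 SS arrays for 764 probe sets and below for 396, which is 6.39% of those tested. Free relabeling of 8 arrays gives 2.86% by chance, and simulated unchanged values centred by batch gave 4.49%. The 17 other splits with both batches balanced gave 1.81% to 10.5%, 3 of them at least 6.39%. Across probe sets, which are not independent, the differences within batch 1 and within batch 2 correlated at 0.080 and had one sign in 45.6%.

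Camera called 19 of the 51 lists at its preset correlation, 15 higher and 4 lower in AA. With a correlation estimated per list it called 0, with 2 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.561. Fry called 0 as well, with 5 at an unadjusted p under 0.05 and a smallest adjusted p of 0.362. Array weights and an adipose covariate did bring probe sets past the threshold. Array weights gave 103 higher and 74 lower, in a fit that stopped before it converged and gave SS replicate 2 a weight of 11.5 against 0.273 to 1.53 in the other arrays. A fit with the adipose list mean as a covariate, added after the data were seen, gave 131 higher and 64 lower.

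**Figure D1:**
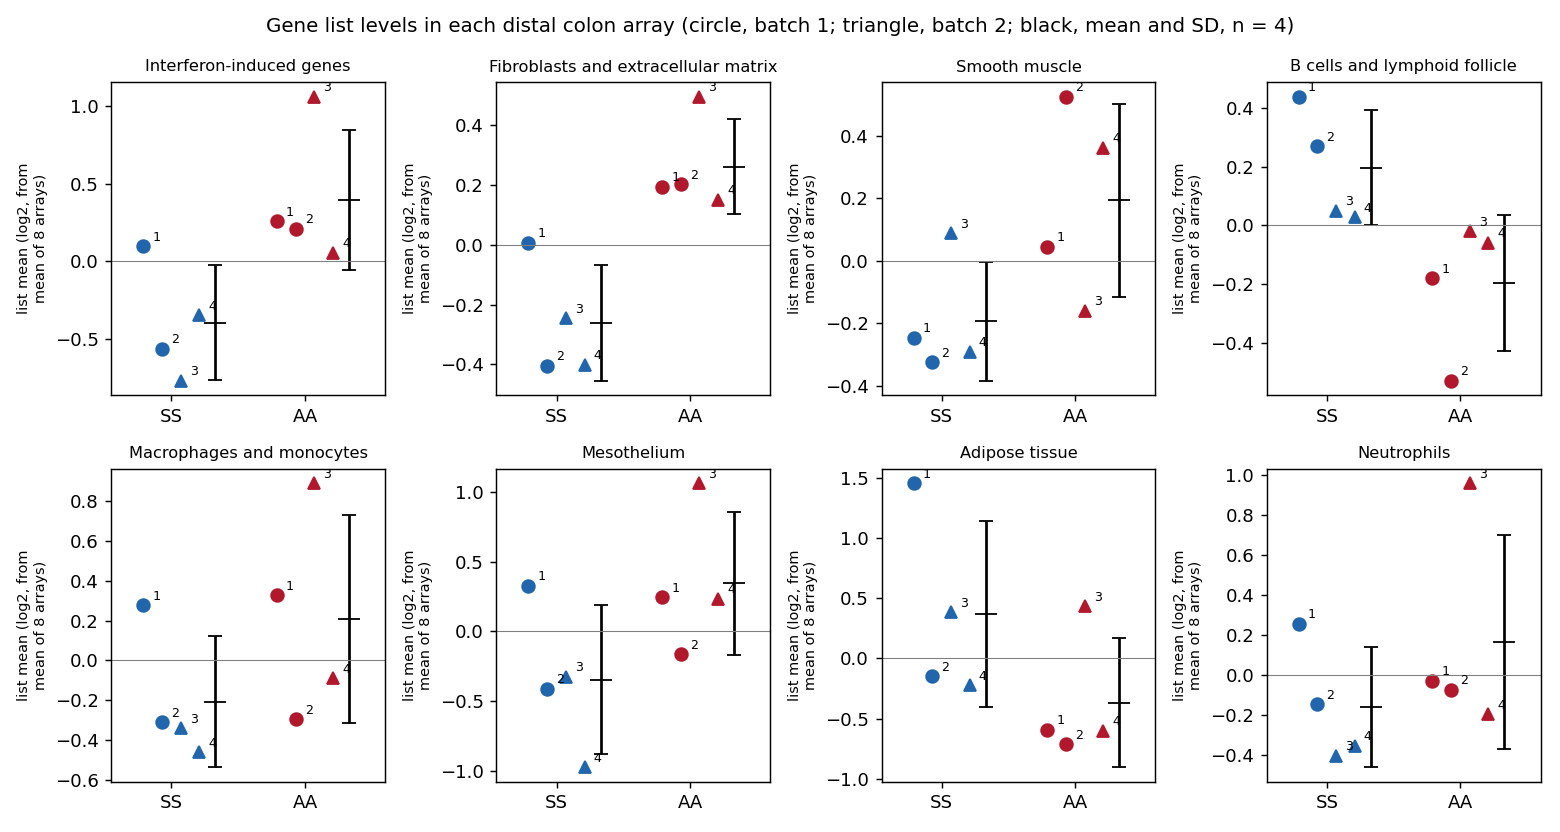
Mean log2 level of 8 gene lists in each array, relative to the mean of the 8 arrays, for SS (blue) and AA (red); circles are batch 1, triangles batch 2, numbers are replicates, and black bars are the mean and SD of 4 arrays. The fibroblast and matrix list runs from 0.15 to 0.50 in AA and from -0.40 to 0.01 in SS, while in the adipose list SS replicate 1 stands at 1.45.

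Interferon-induced genes were higher in AA in 26 of 26 measured members, 24 of them at an unadjusted p under 0.05. Adjusted over the list alone 21 passed, and over all genes 0. Rsad2, an antiviral enzyme also called viperin, stood at 9.30 ± 0.66 (SD, n = 4) in AA and 7.97 ± 0.38 (SD, n = 4) in SS, a 2.52-fold difference. Irf7, the transcription factor that amplifies type I interferon production, differed by 0.78 ± 0.19 (SE), Oas3, an enzyme activated by double-stranded RNA, by 0.89 ± 0.24 (SE), and Oasl1, a member of the same family, by 0.49 ± 0.12 (SE). In each of these 4 genes every AA array lay above every SS array, but they were picked by the smallest p, which favours such separation. The list's median difference was 0.43 in batch 1 and 1.00 in batch 2. Its camera adjusted p was 2.64e-19, against an adjusted p = 0.561 (unadjusted 0.0660) with an estimated correlation. The list mean was highest in AA replicate 3, at 1.06, and SS replicate 1, at 0.10, lay above AA replicate 4, at 0.06. Without AA replicate 3 the median was 0.49, and with the mean of the macrophage or mesothelium list as a covariate it was 0.42 or 0.40.

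Genes of MHC class I antigen presentation were higher in 9 of 10 members, by a median of 0.18, with 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone. B2m, the light chain of class I molecules, differed by 0.32 ± 0.11 (SE), and the immunoproteasome subunits Psmb8 and Psmb9 by 0.46 ± 0.17 (SE) and 0.40 ± 0.16 (SE). The list's median was 0.11 in batch 1 and 0.29 in batch 2. Its camera adjusted p of 0.00437 became an adjusted p = 0.639 with an estimated correlation. The preset call was also lost without AA replicate 3 (median 0.10) or SS replicate 3 (0.11), in batch 1 alone, with quantile normalization (0.13) and with the macrophage or mesothelium covariate (both 0.09).

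Fibroblast and matrix genes were higher in AA in 24 of 24 members, 16 at an unadjusted p under 0.05. Adjusted over the list alone 12 passed, and over all genes 0. The fibrillar collagen genes Col1a2 and Col3a1 differed by 0.79 ± 0.17 (SE) and 0.73 ± 0.16 (SE), Lum, a small proteoglycan of collagen fibrils, by 0.76 ± 0.16 (SE), and Loxl1, which crosslinks elastin, by 0.78 ± 0.17 (SE). Col1a2 stood at 10.89 ± 0.20 (SD, n = 4) in AA and 10.11 ± 0.32 (SD, n = 4) in SS. The median was 0.32 in batch 1 and 0.64 in batch 2, and the list mean of every AA array exceeded that of every SS array. Its camera adjusted p was 1.91e-16, against an adjusted p = 0.561 (unadjusted 0.0207) with an estimated correlation, the smallest unadjusted p of the 51 lists in that test. The median was 0.27 with the mesothelium covariate and 0.68 with the adipose covariate.

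Smooth muscle genes were higher in 20 of 20 members, 11 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Cnn1, an actin-binding protein of contractile cells, differed by 0.64 ± 0.18 (SE), and Hspb7, a small heat shock protein of muscle, by 0.59 ± 0.18 (SE). The median was 0.53 in batch 1 and 0.21 in batch 2, and AA replicate 2 was highest at 0.53. The camera adjusted p of 3.25e-10 became an adjusted p = 0.561 (unadjusted 0.132) with an estimated correlation. Without AA replicate 2 the median was 0.24, and without that array and SS replicate 4 it was 0.16. Markers of mesothelium, the lining of the outer colon wall, were higher in 8 of 9 members, with a median of 0.69 and 4 at an unadjusted p under 0.05. Upk1b, Muc16 and Msln differed by 1.46 ± 0.49 (SE), 1.17 ± 0.46 (SE) and 0.81 ± 0.33 (SE). The mesothelial median was 0.06 in batch 1, where the call was lost, and 1.497 in batch 2, where AA replicate 3 had the highest list mean (1.06) and SS replicate 4 the lowest (-0.98). Its camera adjusted p of 0.000801 became an adjusted p = 0.596 with an estimated correlation. Without SS replicate 4 the median was 0.36, and without AA replicate 3 it was 0.42.

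B cell and lymphoid follicle genes were lower in AA in 15 of 16 members, 9 at an unadjusted p under 0.05. Adjusted over the list alone 5 passed, and over all genes 0. Ms4a1, which encodes the B cell surface protein CD20, stood at 5.54 ± 0.50 (SD, n = 4) in AA and 6.71 ± 0.18 (SD, n = 4) in SS, or 0.443 of the SS level. Cr2, the complement receptor of B cells and follicular dendritic cells, differed by -1.04 ± 0.20 (SE), Fcer2a, a low-affinity IgE receptor, by -0.73 ± 0.17 (SE), and Cd79a, part of the B cell receptor, by -0.43 ± 0.11 (SE). All 4 AA arrays lay below all 4 SS arrays in each of these 4 genes and in the list mean. The 4 genes were picked by the smallest p, which favours such separation. Ms4a1, Cr2 and Fcer2a were dim, with means in both groups below 7.13, the median level of the tested probe sets. With a filter at that level the list kept too few members for a value. The list median was -0.55 in batch 1 and -0.01 in batch 2. Its camera adjusted p of 3.25e-10 became an adjusted p = 0.561 (unadjusted 0.0608) with an estimated correlation, and the preset call was lost in batch 2 alone. T cell genes had a median of -0.09 with 13 of 16 lower and were not called by camera at its preset correlation (adjusted p = 0.0615) or with an estimated one (adjusted p = 0.673). At the preset correlation, the only one used without single arrays, they were called, at -0.14, -0.15 and -0.14, without AA replicate 4, SS replicate 2 or SS replicate 4, and without SS replicate 1 their median was 0.0049. Plasma cell genes were higher in 10 of 12 members by a median of 0.17 (0.16 in batch 1 and 0.08 in batch 2), with 0 at an unadjusted p under 0.05 in limma. The plasma cell call (camera adjusted p = 0.0349) was lost with an estimated correlation, at an adjusted p = 0.561, and without AA replicate 1 (median 0.11), AA replicate 4 (0.10), SS replicate 1 (0.10) or SS replicate 3 (0.16).

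Outside the lists, the genes with the smallest p in the higher direction were led by Tubb6, a beta tubulin, at 0.77 ± 0.10 (SE), and Col5a2, a fibrillar collagen chain, at 0.62 ± 0.09 (SE). None of the 12 passed the threshold, and their adjusted p-values in limma were 0.199 to 0.237. The largest of these differences was in Ifi27l2a, an interferon-induced gene, at 10.05 ± 0.23 (SD, n = 4) in AA and 8.80 ± 0.44 (SD, n = 4) in SS. Clca4a, a calcium-activated chloride channel regulator, stood at 11.02 ± 0.31 (SD, n = 4) and 10.02 ± 0.16 (SD, n = 4), a 2.00-fold difference. Ube2l6, which conjugates the interferon-induced modifier ISG15, differed by 0.94 ± 0.14 (SE), Capg, an actin-capping protein, by 0.84 ± 0.12 (SE), and Plod2, which hydroxylates collagen lysines, by 0.69 ± 0.11 (SE). The others were Ly6m (0.97), Tmem100 (0.94), Crip2 (0.67), Tubb2a (0.66) and Kdelr3 (0.52), and in all 12 genes every AA array lay above every SS array. Selection by the smallest p favours such separation, so it is no added evidence.

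In the lower direction, Hmcn1, which encodes the large extracellular protein hemicentin-1, had 11 of the 12 leading probe sets. The array carries 75 probe sets for this gene. Of these, 68 were lower in AA and 60 were so at an unadjusted p under 0.05, with a median difference of -0.68 and a smallest adjusted p of 0.199. The median over these probe sets ran from 6.26 to 6.68 in the AA arrays and from 6.84 to 7.39 in the SS arrays. Read with 1 probe set per gene, the 12 lower genes with the smallest p also held Cr2, Ms4a1 and Fcer2a, with Atp7b, a copper-transporting ATPase, at -0.45 ± 0.09 (SE) and Neo1, the netrin receptor neogenin, at -0.46 ± 0.09 (SE). These 12 genes had adjusted p-values of 0.199 to 0.298 in limma.

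**Figure D2:**
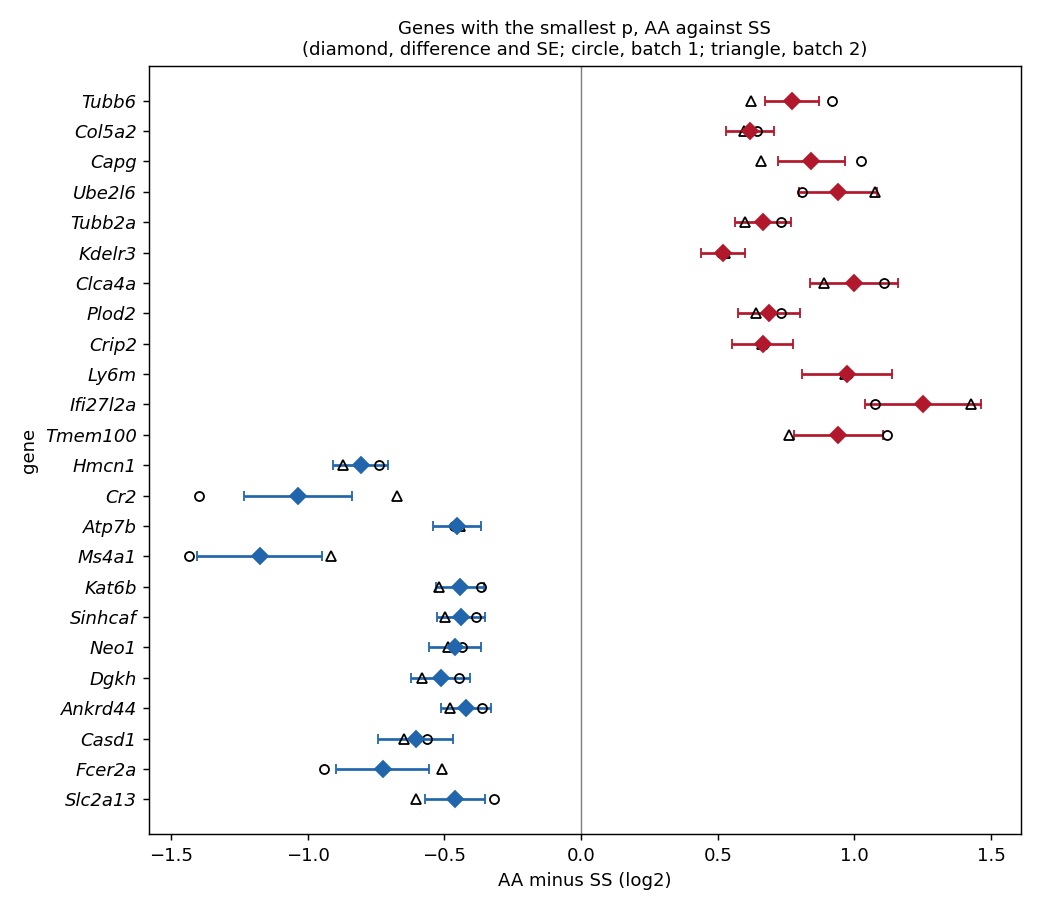
Log2 difference AA minus SS with its standard error (diamonds) for the 12 higher probe sets with the smallest p and for 12 lower genes read with 1 probe set per gene; open circles and triangles are the differences within batch 1 and batch 2. Within both batches each gene has the sign of its overall difference, which was a condition of its selection; Ms4a1 is at -1.43 in batch 1 and -0.92 in batch 2.

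Macrophage and monocyte genes were higher in 18 of 19 members, by a median of 0.44, with 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone. C1qc, a complement component made by macrophages, differed by 0.69 ± 0.26 (SE) and Adgre1, which encodes F4/80, by 0.70 ± 0.29 (SE). The median was 0.02 in batch 1 and 0.96 in batch 2. Complement genes were higher in 11 of 12 members, by a median of 0.45, and neutrophil genes in 14 of 14, by a median of 0.17. In both of these lists 0 genes had an unadjusted p under 0.05. The complement median was -0.04 in batch 1 and 0.91 in batch 2, and the neutrophil median was -0.06 and 0.40, so both turned in sign between the batches. AA replicate 3 had the highest mean of the 8 arrays in all 3 lists, at 0.89, 0.87 and 0.96. Without it the medians were 0.14, 0.13 and -0.0013, none of them called. The complement call was also lost without SS replicate 3 (0.40) or SS replicate 4 (0.30), and the neutrophil call without either (0.12 and 0.14). S100a8, a neutrophil calcium-binding protein, stood at 6.35 ± 1.36 (SD, n = 4) in AA and 5.46 ± 0.69 (SD, n = 4) in SS, a difference within the spread of the AA arrays that was 0.0881 without AA replicate 3. The camera adjusted p-values of 5.54e-05, 0.00912 and 0.0258 all became an adjusted p = 0.673 with an estimated correlation. Genes of Toll-like receptors and the inflammasome were higher in 17 of 22 members, by a median of 0.17, with 2 at an unadjusted p under 0.05 and medians of 0.22 in batch 1 and 0.07 in batch 2. Their camera adjusted p of 0.0317 became an adjusted p = 0.639 with an estimated correlation, and the call was lost without AA replicate 1 (median 0.09), AA replicate 3 (0.10) or SS replicate 1 (0.12).

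Enteric neuron genes were higher in 15 of 17 members, by a median of 0.26, with 7 at an unadjusted p under 0.05 and 1 adjusted over the list alone. That gene was Tac1, the precursor of substance P, at 9.15 ± 0.18 (SD, n = 4) in AA and 8.65 ± 0.06 (SD, n = 4) in SS. Ret, the receptor kinase of enteric nervous system development, differed by 0.31 ± 0.10 (SE). The median was 0.23 in batch 1 and 0.29 in batch 2, and every AA list mean exceeded every SS list mean. Immediate early genes were higher in 19 of 21 members, by a median of 0.24, with 3 adjusted over the list alone. Named here are 3 of the 4 members with the smallest p, not all of which passed. Ier3 differed by 0.56 ± 0.10 (SE), Ccn1, a secreted matrix-associated protein, by 1.10 ± 0.26 (SE) and Egr1, a transcription factor of early responses, by 0.42 ± 0.14 (SE). The median of the immediate early list was 0.23 in batch 1 and 0.20 in batch 2. The camera adjusted p-values of 1.35e-05 for neurons and 1.43e-05 for immediate early genes both became an adjusted p = 0.561 (unadjusted 0.0867 and 0.0270) with an estimated correlation. The neuron median was 0.16 without AA replicate 4, and the immediate early median 0.15 without AA replicate 3.

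Among other stress and growth lists, heat shock genes were higher in 13 of 15 members by a median of 0.14, with Hspb1 at 0.81 ± 0.19 (SE) the 1 gene that passed adjusted over the list alone. Apoptosis and p53 target genes were higher in 15 of 16 by a median of 0.11, with 0 adjusted over the list alone. Hypoxia and glycolysis genes were lower in 12 of 16 by a median of -0.09. Ankrd37 and Pdk1, both targets of the hypoxia-inducible factor, differed by -0.52 ± 0.12 (SE) and -0.49 ± 0.13 (SE), and these 2 passed adjusted over the list alone. Cell cycle genes were higher in 25 of 26 by a median of 0.12, with 0.38 in batch 1 and -0.15 in batch 2. The within-batch medians were 0.16 and 0.09 for heat shock, 0.28 and 0.07 for apoptosis, and -0.23 and -0.08 for hypoxia. The camera adjusted p-values were 0.00367, 0.00129, 0.00161 and 0.0317 in that order. With an estimated correlation they became an adjusted p = 0.561 for heat shock, apoptosis and hypoxia and 0.673 for the cell cycle. The heat shock call was lost without AA replicate 3 (median 0.05), and the cell cycle call without AA replicate 1 (0.04), AA replicate 2 (0.08), SS replicate 1 (0.03) or SS replicate 2 (0.09).

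Epithelial lists were not called. Absorptive colonocyte genes had a median of 0.11 with 19 of 25 higher (camera adjusted p = 0.0736), and goblet cell genes a median of 0.05 with 9 of 14 higher (adjusted p = 0.496). Both medians were positive in batch 1, at 0.25 and 0.12, and negative in batch 2, at -0.03 and -0.10. Lists of T helper and regulatory responses were not called either. The Th17 and IL-23 list had a median of -0.03 with 6 of 10 members lower (adjusted p = 0.420). The Th1 list had a median of 0.08 (adjusted p = 0.363), the regulatory T cell list 0.05 (adjusted p = 0.222) and the list of acute cytokines and NF-kB targets 0.06 (adjusted p = 0.956 with an estimated correlation). Adjusted over the list alone, 2 regulatory T cell genes passed as higher and 1 Th17 gene as lower. In the Th1 and acute cytokine lists 0 passed. Of the 16 measured genes of the fixed panel, 1 had an unadjusted p under 0.05. This was Ccl20, the chemokine that draws CCR6-bearing lymphocytes to follicles, at 7.68 ± 0.29 (SD, n = 4) in AA and 8.41 ± 0.33 (SD, n = 4) in SS, with an adjusted p of 0.336 in limma. Il17a differed by 0.14 ± 0.11 (SE), Il17f by -0.17 ± 0.10 (SE), Il23a by -0.05 ± 0.11 (SE), Il13 by -0.22 ± 0.14 (SE), Tnf by 0.11 ± 0.12 (SE) and Foxp3, the transcription factor of regulatory T cells, by -0.09 ± 0.09 (SE). The group means of these 6 genes were 5.44 to 6.47, in a table whose values run from 2.85 to 14.72. All lay below the array medians of 6.93 to 6.99, so it is not settled whether these genes were expressed.

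Markers of neighbouring tissues varied between arrays. The adipose list mean was 1.45 in SS replicate 1, 0.43 in AA replicate 3 and 0.38 in SS replicate 3, and below 0 in the other 5 arrays. Adipose genes were lower in AA in 14 of 14 members, 0 of them at an unadjusted p under 0.05, with a median of -1.34 in batch 1 and -0.12 in batch 2. Car3 stood at 8.65 ± 1.75 (SD, n = 4) in AA and 10.42 ± 1.12 (SD, n = 4) in SS, and Adipoq, the adiponectin gene, reached 10.04 in SS replicate 1. Without SS replicate 1 the adipose median was -0.19. Genes of the male accessory glands, such as the seminal vesicle and prostate, were lower in 8 of 9 members, with a median of -0.80 (-0.01 in batch 1 and -1.54 in batch 2) that was 0.0081 without SS replicate 4. Tgm4, the prostate transglutaminase, stood at 7.49 in SS replicate 4 and between 4.83 and 5.93 in the other 7 arrays. One of the 9 gland genes, Spink1, named here after its values were seen, was at a mean of 12.31 in AA and 12.20 in SS and so is also expressed in this tissue. The camera adjusted p-values of 1.80e-05 and 0.00912 became an adjusted p = 0.561 for adipose genes and 0.673 for gland genes with an estimated correlation.

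**Figure D3:**
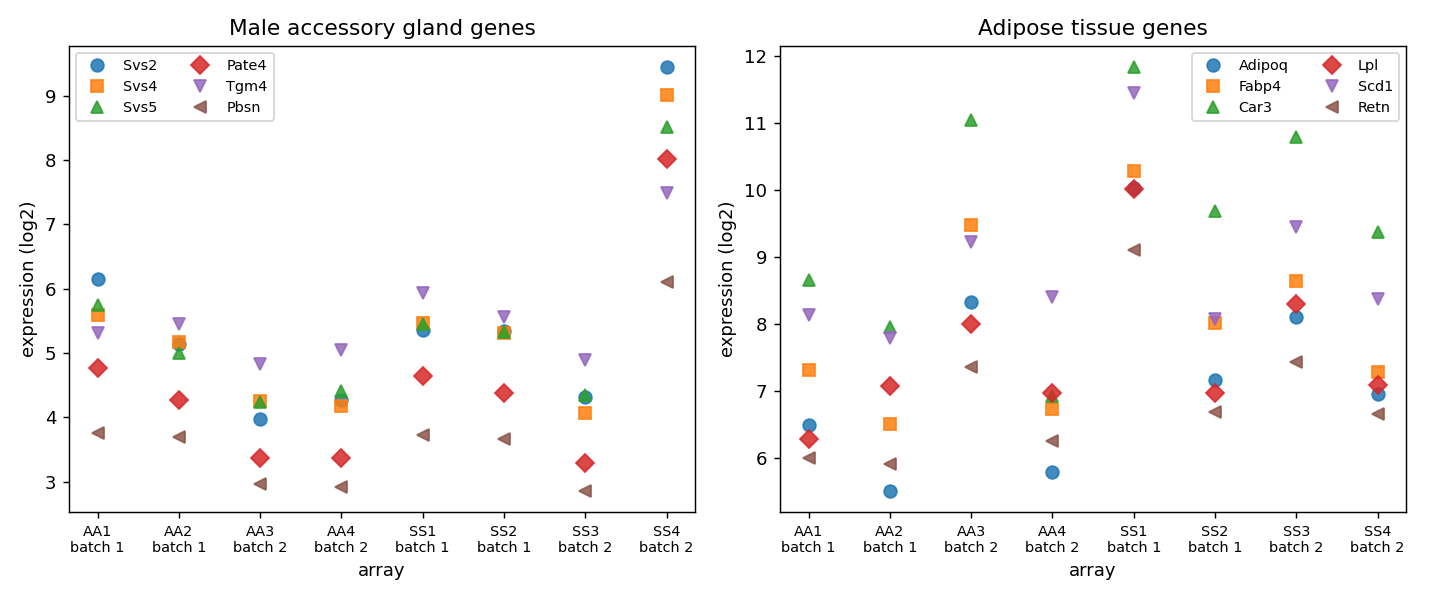
Log2 expression in each array of 6 genes of the male accessory glands (left) and 6 of adipose tissue (right), with the batch under each array. Svs2 is at 9.45 in SS replicate 4 and at 3.97 to 6.15 elsewhere, and Adipoq is highest in SS replicate 1 (10.04) and next highest in AA replicate 3 (8.34).

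The authors' deposited table listed 266 entries for 260 distinct gene sets raised in AA, under 21 themes, with NES from 1.70 to 2.58 and q-values up to 0.01. The interferon theme of the authors' deposited table held 14 entries, with NES of 2.01 to 2.40. The authors' deposited table placed 6 entries under protein metabolism and antigen processing, and its highest-scoring proteasome set had an NES of 2.43. Another 6 entries of the authors' deposited table stood under adhesion and extracellular matrix, at 1.88 to 2.13, and 5 under NF-kB, at 1.78 to 2.11. As the authors chose these sets on this same series, they are no independent evidence of direction. In the lists fixed here, interferon-induced and matrix genes had positive medians (0.77 and 0.45). The acute cytokine and NF-kB list had a median of 0.06 and was not called. The 16 measured hypoxia and glycolysis genes had a negative median, of -0.09. The authors' deposited table gave the raised sets MANALO_HYPOXIA_UP and HYPOXIA_RCC_NOVHL_UP an NES of 1.92 and 1.89, with 87 and 62 enriched genes. Those sets were not scored here, and they differ from the list fixed here in members and in measure, so the values do not show a conflict.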

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

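Values are given here where 1 array lay far from the other 3 of its group, relative to the group's range, a rule set before the data were seen; none was weighed further. Of 164 groups of 4 arrays checked, 9 held such a value. Chance gives about 1 in 20, or 8.2 here, so their number is near that of chance.

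AA replicate 3 held 5 of the 9. Upk1b, a mesothelial gene, was at 9.58 there and at 7.61 to 7.84 in the other AA arrays. Col3a1 was at 11.44 against 11.11 to 11.15. The mean of the fibroblast and matrix list was 0.50 above the mean of the 8 arrays, against 0.15 to 0.20, and that of the neutrophil list 0.96 against -0.20 to -0.03. The adipose list mean was 0.43 against -0.71 to -0.59 in the other AA arrays. In SS replicate 1, Capg was at 8.09 against 8.48 to 8.54 in the other SS arrays, and Psmb9 at 8.83 against 8.37 to 8.44. Egr1 was at 7.20 in AA replicate 4 against 7.60 to 7.65 in the other AA arrays. The regulatory T cell list mean was -0.0802 in AA replicate 2 against 0.0758 to 0.0972 in the others.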

How the results depend on the processing

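Settings added after the data were seen were those that leave out 2 arrays, use 1 probe set per gene, or add a list mean as a covariate. Probe sets past the adjusted threshold in limma numbered 0 higher and 0 lower without any one array and in the other settings, except with array weights (103 and 74), the adipose covariate (131 and 64), the macrophage covariate (5 and 3) and the mesothelium covariate (1 and 4). An unadjusted p under 0.05 with a fold change of at least 1.5 took 145 and 73. The replicate block left 0 and 0 past the threshold, with 875 higher and 369 lower at an unadjusted p under 0.05 and 23 lists called. The labels give no pairing by replicate number. Deviations of same-numbered AA and SS arrays correlated at -0.32, -0.09, -0.44 and -0.22, where simulated unpaired values centred by batch gave -0.20 within a batch and 0.20 between batches, so that 0 of 4 AA arrays correlating best with their own number is no evidence against pairing. Within the batch, 1 of 4 AA arrays correlated better with its own number than with the other. The planned median over deposited raised genes was not run in any setting, since that table names sets, and at the median level filter the B cell list kept too few members for a value.

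Lists called were 12 to 24 without one array, lowest without AA replicate 3, and 0 with an estimated correlation and 0 with fry. In the other settings the preset calls of the interferon, matrix, smooth muscle, neuron and immediate early lists held. Those settings kept the preset correlation of 0.01, while the correlations estimated per list were 0.77, 0.31, 0.81, 0.31 and 0.09 in that order. As refits of the same 8 arrays, they are no independent evidence for these calls. Probe sets at an unadjusted p under 0.05 numbered 585 to 1013 higher and 322 to 1121 lower without one array, with the higher count lowest without SS replicate 4, the lower count lowest without SS replicate 2, and both highest without SS replicate 1. Lower ones numbered 751 with no batch term, 252 above the median level, 781 with quantile normalization, 1408 in batch 2 alone, 788 with the mesothelium and 1060 with the adipose covariate. Array weights gave 1602 higher and 1396 lower. Without AA replicate 3 and SS replicate 1 there were 998 and 870, and without AA replicate 2 and SS replicate 4, 502 and 245. Over the values of single lists in all these settings, 513 stayed on their side of the threshold, 99 no longer passed it, 24 newly passed and 36 turned in sign.

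The signs that turned are given here, and the cause was not tested. Ranges without one array were -1.25 to 0.00808 for gland genes, -0.00131 to 0.29 for neutrophils, -0.15 to 0.00494 for T cells, -0.0195 to 0.15 for Th1, -0.0789 to 0.0402 for Th17, -0.0177 to 0.13 for NF-kB targets, -0.0289 to 0.0832 for goblet cells, -0.12 to 0.0393 for Il23a and -0.000065 to 0.18 for Tnf. In batch 1 alone complement was at -0.0424, neutrophils -0.0611, Th1 -0.043, NF-kB targets -0.0852, regulatory T cells -0.0264, S100a8 -0.0401 and Tnf -0.0671. In batch 2 alone the cell cycle was at -0.15, T cells 0.0119, colonocytes -0.0256, goblet cells -0.0984, Th17 0.0626, Il17f 0.0109, Il23a 0.009 and Foxp3 0.00448. With the mesothelium covariate macrophages were at -0.0536, complement -0.12, gland genes 0.00397, neutrophils -0.15, Th1 -0.0959, NF-kB targets -0.13, regulatory T cells -0.0494, S100a8 -0.26 and Tnf -0.0833. With the macrophage covariate neutrophils were at -0.0338, Th1 -0.0701, NF-kB targets -0.0624, S100a8 -0.0133 and Tnf -0.028. With the adipose covariate the cell cycle was at -0.0489, T cells 0.00995, colonocytes -0.0124, goblet cells -0.0635 and Il23a 0.0179. Without AA replicate 2 and SS replicate 4 gland genes were at 0.16 and Th17 at 0.0374, and without AA replicate 3 and SS replicate 1 T cells were at 0.0192. Goblet cells were at -0.0025 with array weights, and Th1 at -0.00815 above the median level.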

Other observations

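The tests of explanations, the exact permutation, the proteasome list and the splits of the arrays were chosen after the results were seen. A list of 47 proteasome genes was made after the authors' deposited table was read. It took all numbered symbols from Psma to Psmg, so it is not limited to subunits, and it shares Psmb8 and Psmb9 with the MHC class I list. These genes were higher in AA in 40 members, with a median of 0.13 and 8 at an unadjusted p under 0.05. Adjusted over the list alone 0 passed. Camera gave p = 1.15e-07 at its preset correlation and p = 0.116 with an estimated correlation, and fry gave p = 0.0365. Enteroendocrine genes were higher in 11 of 20 members and were not called by camera (adjusted p = 0.287), while the list mean of every AA array exceeded that of every SS array. By exact two-sided permutation within batches, 7 of the 51 lists reached the smallest p possible, 0.0556, and after Benjamini-Hochberg the smallest was 0.354. The list means of the groups did not overlap for 4 lists higher and 1 lower in AA, where free relabeling gives 2.86% of lists by chance, or 1.46, and simulated values centred by batch gave 2.29. The 17 other splits with both batches balanced gave 0 to 10 such lists, 1.88 on average and at least 5 in 1.

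Hoxd13 and Hoxb13, transcription factors of the hindmost body axis, named here after their values were seen, were at 6.54 and 8.23 in AA replicate 2. In the other 7 arrays they were at 8.82 to 10.63 and at 9.63 to 10.61. Hoxa13 was at 8.31 in that array, within the 7.88 to 8.50 of the others, and Hoxd12, Hoxc12 and Hoxc13 were also within the range of the others. Hoxd10 and Hoxd11 were lowest there at 6.90 and 6.88, and Hoxa10 and Hoxa11 highest at 7.81 and 6.75, each close to the range of the others.

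The 8 arrays make 35 splits into 4 and 4, of which 18 hold equal numbers of each batch, as the real one does. At least 1467 probe sets at an unadjusted p under 0.05 were found in 6 of the 35 and 4 of the 18, with up to 2374 in another split, so chance is not excluded for that count. The 19 called lists were matched in 12 of the 35 and 6 of the 18, with up to 30 in another, so chance is not excluded for the number of camera calls. All 35 splits gave 0 probe sets past the threshold in limma. With array weights 177 probe sets passed in the real split and at most 5 in another, 1 of 35, and with the adipose covariate 195 passed against at most 2, also 1 of 35. In the other 17 splits with balanced batches both fits gave 0, and 18 splits are too few for a share under 0.05. The fits shared 93 probe sets, each with the same sign in both, against 1.90 for independent lists, though both were made from the same arrays. Both fits also set SS replicate 1 apart, as it had the lowest weight, 0.273, and the highest adipose list mean, 1.45. The overlap therefore does not single out fat. Hmcn1 made up 48 of the 177 and 45 of the 195, and matrix genes 7 and 9. As the weights did not converge and the covariate was picked after the data were seen, it stays a hypothesis that variation in fat hides differences between the groups. The matrix genes had a list mean difference of 0.52 ± 0.14 (SE, 95% interval 0.17 to 0.88), and 4 of the 35 splits and 3 of the 18 gave a median as large as 0.45, up to 0.57, so chance is not excluded.

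The higher level of interferon-induced genes in AA had a list mean difference of 0.79 ± 0.32 (SE), with a 95% interval of -0.03 to 1.61 that itself includes 0. A median difference as large as 0.77 appeared in 2 of the 35 splits, up to 0.94, so chance is not excluded, and in 1 of the 18 with balanced batches, next 0.65. With the adipose list mean as a covariate the difference was 1.15 ± 0.26 (SE). Within that fit this argues against fat in the tissue piece as the whole cause. The covariate was picked after the data were seen. SS replicate 1 stood highest in it, at 1.45 against 0.43 in AA replicate 3, so that array weighs heavily in the fit. AA replicate 3 stays open, as without it the list mean difference was 0.53 ± 0.22 (SE). More macrophages in the AA pieces stay open as well, at 0.46 ± 0.21 (SE) with the macrophage list mean as a covariate. Both of these 95% intervals include 0. A response to appendicitis or to removal of the appendix may also account for the higher level and was not tested apart from these explanations. As no group had either alone, appendicitis and removal cannot be told apart.

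The lower level of B cell and follicle genes had a list mean difference of -0.39 ± 0.17 (SE, 95% interval -0.82 to 0.03), and 3 of the 35 splits, all 3 with balanced batches, gave a median as large as 0.33, up to 0.37, so chance is not excluded. Dilution of the mucosa by muscle or connective tissue stays open, as smooth muscle and matrix genes were higher by medians of 0.38 and 0.45. Against it, 39 colonocyte and goblet cell genes had a median of 0.10. In batch 1, where the B cell median was -0.55, the colonocyte and goblet medians were 0.25 and 0.12. In batch 2, where the B cell median was -0.01, they were -0.03 and -0.10. The 95% interval over arrays of the mean difference of the 39 genes was -0.20 to 0.43. It reaches -0.197, which is 0.5 times the B cell difference, so the test does not decide. Without AA replicate 2, the array with low Hoxd13, the difference was -0.26 ± 0.12 (SE), with an interval that includes 0 as well, so a different position of that piece, which rests on Hox genes picked after their values were seen, stays open. Fewer lymphoid follicles in the pieces, by sampling or by treatment, cannot be told apart from fewer B cells, as the T cell genes had a median of -0.0896 and a list mean difference of -0.0859 ± 0.10 (SE over arrays, 95% interval -0.35 to 0.18), which does not decide.

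In SS replicate 4, 7 of the 9 measured male accessory gland genes lay at least 1 log2 unit above every other array, by 1.56 to 3.43. Svs2, Svs4 and Pate4, named after their values were seen, were at 9.45, 9.02 and 8.02. Gland tissue or RNA in that piece is a candidate source that stays open, since the count of 7 restates the pattern and does not test it. The same genes were lower in the other 3 arrays of batch 2 than in batch 1, by a median of 1.05 and by 0.64 to 1.32. With equal batch means this follows by arithmetic from the high array, and it does not show which step centred the values. No biological explanation of the gland genes was tested.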
